A study of Homo sapiens with 16 samples.

How the data were processed

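RNA sequencing measured transcript levels in 16 libraries of H1, an established human embryonic stem cell line. The cells spent 24 h in E7 medium, which is E8 medium without TGFb, either as it was or with added TGFb at 1.74 ng/mL, Activin A at 100 ng/mL or NODAL at 100 ng/mL, and each of these 4 media was used with and without 2-deoxyglucose (2DG) at 3 mM. This gave 8 groups of 2 libraries. The libraries were made from polyadenylated RNA and read from both ends on an Illumina NextSeq instrument. The labels do not say whether the replicates of a group were separate cultures, so each p-value measures only the spread between these samples.

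The deposited values are a signal made by the authors: read counts per gene divided by 1 size factor per library. The submitters' processing notes name Trimmomatic 0.36, STAR, featureCounts 1.5.3, DESeq2 1.26.0 and the hg38 build, without the role of each, the annotation release, the strand setting or the gene filter. Every value was a whole multiple of the smallest value in its library within a tolerance of 1e-06, for 100% of the values, so whole reads were recovered. The median-of-ratios size factors of these recovered reads equalled the divisors. The table listed 17738 genes, each with at least 1 recovered read in all 16 libraries, so genes without reads in some library were left out before deposit. Because the strand setting is not stated, values of antisense genes such as VLDLR-AS1 and JAKMIP2-AS1 are uncertain. Values of near-identical genes and pseudogenes, among them the MT1 genes, LEFTY1 and LEFTY2, SNRPGP10 and HMGB1P10, depend on how shared reads were assigned.

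Recovered reads per library ranged from 14600479 to 17630329. Mitochondrial genes held 5.46 to 6.69% of the reads. Relative counting error is largest for genes near the minimum value of 10.

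Gene positions, transcript lengths and GC content came from GENCODE 29, in which 17317 of the 17738 symbols (97.6%) matched a single gene. Of the others, 49 symbols had more than 1 gene and 372 were not found. Older symbols in the table were matched to current ones.

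The test used R 4.3.3 and limma 3.58.1 with an intensity trend on log2 of the value plus 1. Genes with a value of at least 10 in at least 2 libraries were kept, which left 16714. A single model with 8 group means was fitted to all 16 libraries, and 13 contrasts were taken from it. The p-values, two-sided, were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The interaction of 2DG with an added factor was the log2 response to 2DG in that medium less the response in E7. Values are given as normalised read counts, mean ± SD over the 2 libraries of a group, and log2 fold changes with the standard error (SE) of the fit.

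Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists within a contrast, with the smallest list tested holding at least 5 genes. The lists covered pluripotency, signalling targets, lineage markers, metabolism, stress responses, cell division, markers of other cell types and RNA quality. An estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were the alternatives. Camera made 102 calls in the 13 contrasts, of which 5 held with an estimated correlation and 80 held with fry. The 5 were the pluripotency core, the TGFb, Activin and Nodal targets, the mesendoderm list and the ribosome biogenesis list for Activin A in E7, and the ribosome biogenesis list for NODAL in E7. For each list, counts are also given adjusted over the list alone.

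The groups, the contrasts, the tests, the lists and the rule for naming genes were chosen before the data were examined. The rule named, for each contrast, the 8 called genes with the largest log2 fold change in each direction among gene symbols whose higher group averaged at least 100 and whose libraries did not overlap between the groups. For an interaction the ranking was by the size of the term, without the overlap condition. It also named up to 4 called members per list with the largest absolute change, and let 12 genes be named in any contrast, called or not, of which the text gives a part: POU5F1, SOX2, NANOG, LEFTY1, LEFTY2, NODAL, TXNIP, HSPA5, DDIT3, PAX6, TBXT and HK2. Any gene named outside this rule is said to be so, and some genes that met it are not reported here.

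The alternatives planned were TMM factors, scaling to the same total, quantile normalization, a pseudocount of 0.5 or 8, no filter, a mean of at least 50, robust fitting, only the libraries of the contrast, the replicate number as a block, an absolute log2 fold change of at least 1, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Each library was also left out in turn. In that case a group with 1 library left was assumed to vary like the other groups. A pairwise check of 28 pairs of groups found a correlation above 0.1 between replicate differences in 3, so the replicate numbers do not pair the samples. Removing the trend with transcript length from each library (lowess span 0.3), weights per library, and leaving out the 4 libraries with Activin A were added after seeing the data. The contrasts of TGFb, Activin A or NODAL against E7 with 2DG present were added as well.

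Simulated data built from the observed spread had 100 genes changed 2-fold and 100 changed 4-fold. For 2DG in E7, limma found 88 of the 2-fold and 99 of the 4-fold changes, and 11 of its 198 calls were false. For TGFb in E7 it found 89 of the 2-fold changes (14 of 203 calls false). For the interaction of 2DG and NODAL it found 46 (13 of 156). In the same order DESeq2 had 23 of 212 and 24 of 180 calls false, and edgeR 12 of 199 and 12 of 156. Replicate differences ran from 1.61 to 57.8 times the counting variance between groups, so these rates may not hold here. All columns of the table were used.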

Results

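The data are normalised read counts of 17738 genes in 16 libraries of H1 human embryonic stem cells, 2 for each of 8 groups. The groups cross 4 media (E7, and E7 with TGFb, Activin A or NODAL) with the presence or absence of 2DG, a glucose analog that cells take up and phosphorylate but cannot carry through glycolysis. TGFb, Activin A and NODAL are secreted ligands that signal through SMAD2 and SMAD3 and help keep human pluripotent cells undifferentiated. Recovered reads were 17407357 and 16606411 for replicates 1 and 2 of E7, 16850731 and 14899899 for E7+2DG, 15415334 and 17325632 for E7+TGFb, and 16447859 and 14967998 for E7+TGFb+2DG. They were 17630329 and 17022118 for E7+ActivinA, 16880069 and 14963071 for E7+ActivinA+2DG, 14600479 and 16236270 for E7+NODAL, and 17289014 and 14907397 for E7+NODAL+2DG.

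Replicates differed most in E7+ActivinA, where the difference between the libraries was 57.8 times the counting variance (chi-square per degree of freedom). The same ratio was 15.8 in E7+ActivinA+2DG, 10.9 in E7, 5.7 in E7+2DG, 3.59 in E7+NODAL, 2.15 in E7+TGFb+2DG, 2.04 in E7+NODAL+2DG and 1.61 in E7+TGFb. In E7+ActivinA the replicate difference also followed transcript length, with Spearman's rho = -0.52 across genes, and in E7 with rho = 0.38. Genes are not independent replicates, so no p is given for a rho across genes. The model pools the spread of all groups, so the Activin A libraries enlarge the error of every contrast.

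**Figure D1:**
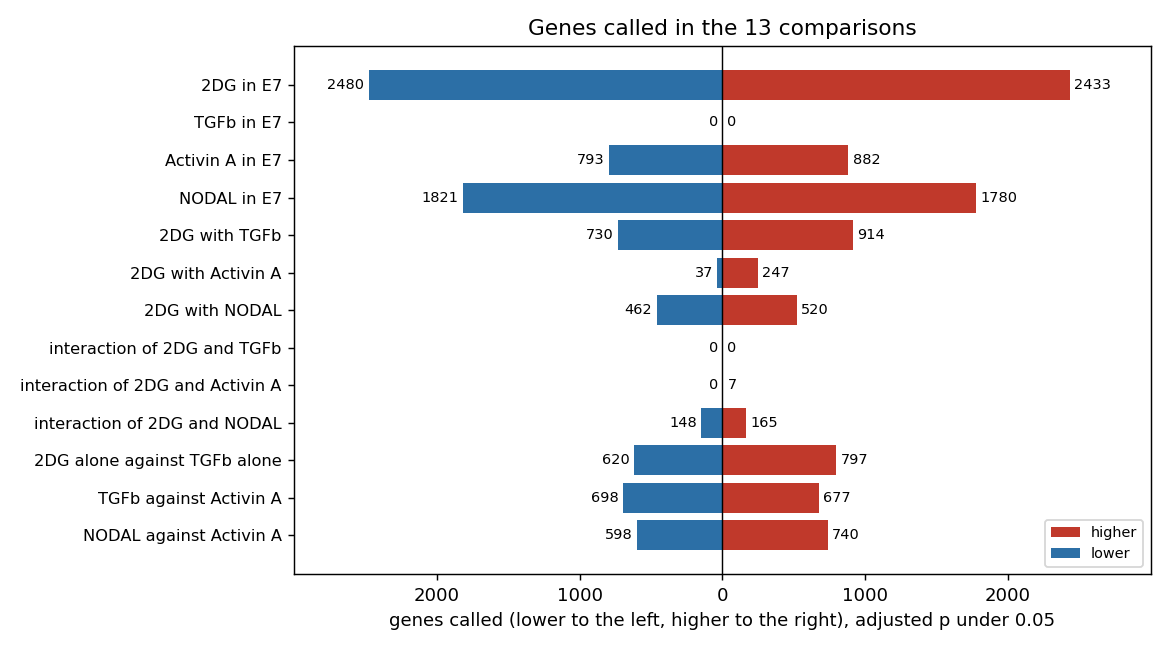
Bars show the number of genes called higher (right) and lower (left) at an adjusted p under 0.05 in each of the 13 comparisons, with the numbers printed. 2DG in E7 had the longest bars, 2433 higher and 2480 lower, and TGFb in E7 had none.

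2DG in E7 addressed what the glucose analog does to these cells without an added ligand. TXNIP, an arrestin-like inhibitor of glucose uptake, rose from 67.5 ± 22.3 to 1670 ± 77.9 normalised reads (SD, n = 2), a log2 fold change of 4.64 (SE 0.25, adjusted p = 5.5e-07). DDIT3, the stress transcription factor also called CHOP, rose from 38.6 ± 8.56 to 375 ± 76.2 (log2 3.25, adjusted p = 0.00042). LEFTY1, a secreted inhibitor of NODAL that is itself a NODAL target, fell from 538 ± 106 to 25.7 ± 6.77 (log2 -4.35, SE 0.26, adjusted p = 1.5e-06). In all, 2433 genes rose and 2480 fell, of 16714 tested.

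The ATF4 amino acid response list had 24 of 25 tested members higher and 0 lower, and the counts adjusted over the list alone were the same (camera adjusted p = 7.5e-15). That call was lost, with adjusted p = 0.38 with an estimated correlation. Its largest rises were ATF5 (3.68), DDIT3, DDIT4 (3.13) and the cystine transporter SLC7A11 (2.93). The ER unfolded protein response list had 10 of 20 higher and 0 lower, 11 and 0 adjusted over the list alone (camera adjusted p = 4.4e-05, and adjusted p = 0.38 with an estimated correlation). It included HERPUD1 (1.42), the ubiquitin ligase SYVN1 (1.02), HYOU1 (0.99) and the ER chaperone HSPA5, which went from 18000 ± 572 to 25100 ± 1160 (log2 0.47, adjusted p = 0.0028). The glucose sensing list had TXNIP and ARRDC4 (3.78) called higher among 6 members, 4 adjusted over the list alone (camera adjusted p = 0.0057, and adjusted p = 0.38 with an estimated correlation). TAC1, a precursor of tachykinin peptides, rose by 4.48, the amino acid transporter gene SLC1A4 by 3.91 and INHBE, an inhibin beta subunit, by 3.83.

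With 2DG in E7, LEFTY2 fell by 3.86 on the log2 scale and NODAL by 1.57, from 795 ± 42.5 to 268 ± 33.6 (adjusted p = 0.00023). The list of TGFb, Activin and Nodal targets had 4 of 18 higher and 7 lower, 4 and 8 adjusted over the list alone, and was not called as a set (camera adjusted p = 0.079). The mesendoderm list had 1 of 14 higher and 6 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.38 with an estimated correlation), with falls in FGF8 (-1.93), MIXL1 (-1.71) and HHEX (-1.18). HEY1, a Notch target, fell by 2.97. The pluripotency factors POU5F1 (-0.46, adjusted p = 0.037) and NANOG (-0.47, adjusted p = 0.0062) fell, and SOX2 had a log2 fold change of -0.02 (adjusted p = 0.88). The pluripotency core list had 4 of 20 higher and 7 lower by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.6). The NANOG call was lost without E7 replicate 2 (adjusted p = 0.068) or E7+2DG replicate 1 (adjusted p = 0.057). That of POU5F1 was lost without E7 replicate 2 (adjusted p = 0.23), E7+2DG replicate 1 (adjusted p = 0.18) or its replicate 2 (adjusted p = 0.082), with E7+NODAL+2DG or E7+TGFb+2DG short of either replicate (adjusted p = 0.053) and with E7+TGFb short of either replicate (adjusted p = 0.054). The naive pluripotency list had 3 of 13 higher and 2 lower, 6 and 2 adjusted over the list alone (camera adjusted p = 0.29), with KLF4 higher (1.19). Of the primed pluripotency list 8 of 20 were higher and 2 lower, 8 and 4 adjusted over the list alone (camera adjusted p = 0.45), with OTX2 higher (0.99).

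With 2DG in E7 the S phase list had 0 of 18 higher and 12 lower, 0 and 13 adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.38 with an estimated correlation), with falls in PCNA (-0.92) and the replication helicase subunit MCM6 (-0.83). The G2 M phase list had 1 of 20 higher and 9 lower, 2 and 9 adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.42 with an estimated correlation), including CDK1 (-0.91) and HMMR (-1.02). The nuclear oxidative phosphorylation list had 0 of 37 higher and 23 lower, 0 and 24 adjusted over the list alone, with a median log2 fold change of -0.50 (camera adjusted p = 3.1e-06, and adjusted p = 0.5 with an estimated correlation). The TCA cycle list had 3 of 23 higher and 12 lower, 3 and 14 adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.49 with an estimated correlation), with FH (-0.74) and SUCLA2 (-0.67) among the falls. Genes of the mitochondrial genome had 2 of 13 higher and 0 lower, also adjusted over the list alone (median 0.06, camera adjusted p = 0.75). The heat shock list had 0 of 12 higher and 8 lower, 0 and 10 adjusted over the list alone (camera adjusted p = 4.4e-05, and adjusted p = 0.42 with an estimated correlation), led by HSPE1 (-1.08) and HSP90AA1 (-0.85). The cholesterol biosynthesis list had 1 of 20 higher and 8 lower, 3 and 11 adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.47 with an estimated correlation), including the sterol enzyme gene IDI1 (-1.01). The ribosome biogenesis list had 1 of 18 higher and 7 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.38 with an estimated correlation). The glycolysis list had 4 of 24 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.68). LDHA was lower (-0.78) and ENO2 higher (0.75). Without E7 replicate 1 the calls of the cholesterol and G2 M phase lists (adjusted p = 0.056 each) and of the ribosome biogenesis list (adjusted p = 0.055) were lost, and without E7+2DG replicate 1 that of the cholesterol list (adjusted p = 0.081). HK2, the hexokinase that phosphorylates glucose and 2DG, had 0.23 (adjusted p = 0.13), and passed the test without E7+ActivinA replicate 1 or replicate 2 (adjusted p = 0.025 each).

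Measures meant for library quality also moved, as did the S phase list, and the cause was not tested. The log2 fold change rose with transcript length (rho = 0.34 across genes). Of the RNA quality list of histone genes without poly(A) tails, 0 of 7 rose and 2 fell, also adjusted over the list alone. The list was called (camera adjusted p = 0.023, and adjusted p = 0.38 with an estimated correlation), but not without E7+2DG replicate 1. Among fibroblast and stromal markers 3 of 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.6), and the largest was COL6A3 (3.49), from 29.2 ± 19.7 to 299 ± 12.8. The remaining lists had camera adjusted p between 0.064 and 0.95, and for the FGF ERK, WNT, p53 and apoptosis lists the median, mean and test differed in sign. The count of 4913 genes became 1586 without E7 replicate 2, 2261 without E7+2DG replicate 1 and 2734 without E7+2DG replicate 2. It was 7590 without the 4 Activin A libraries, a setting added after seeing the data.

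**Figure D2:**
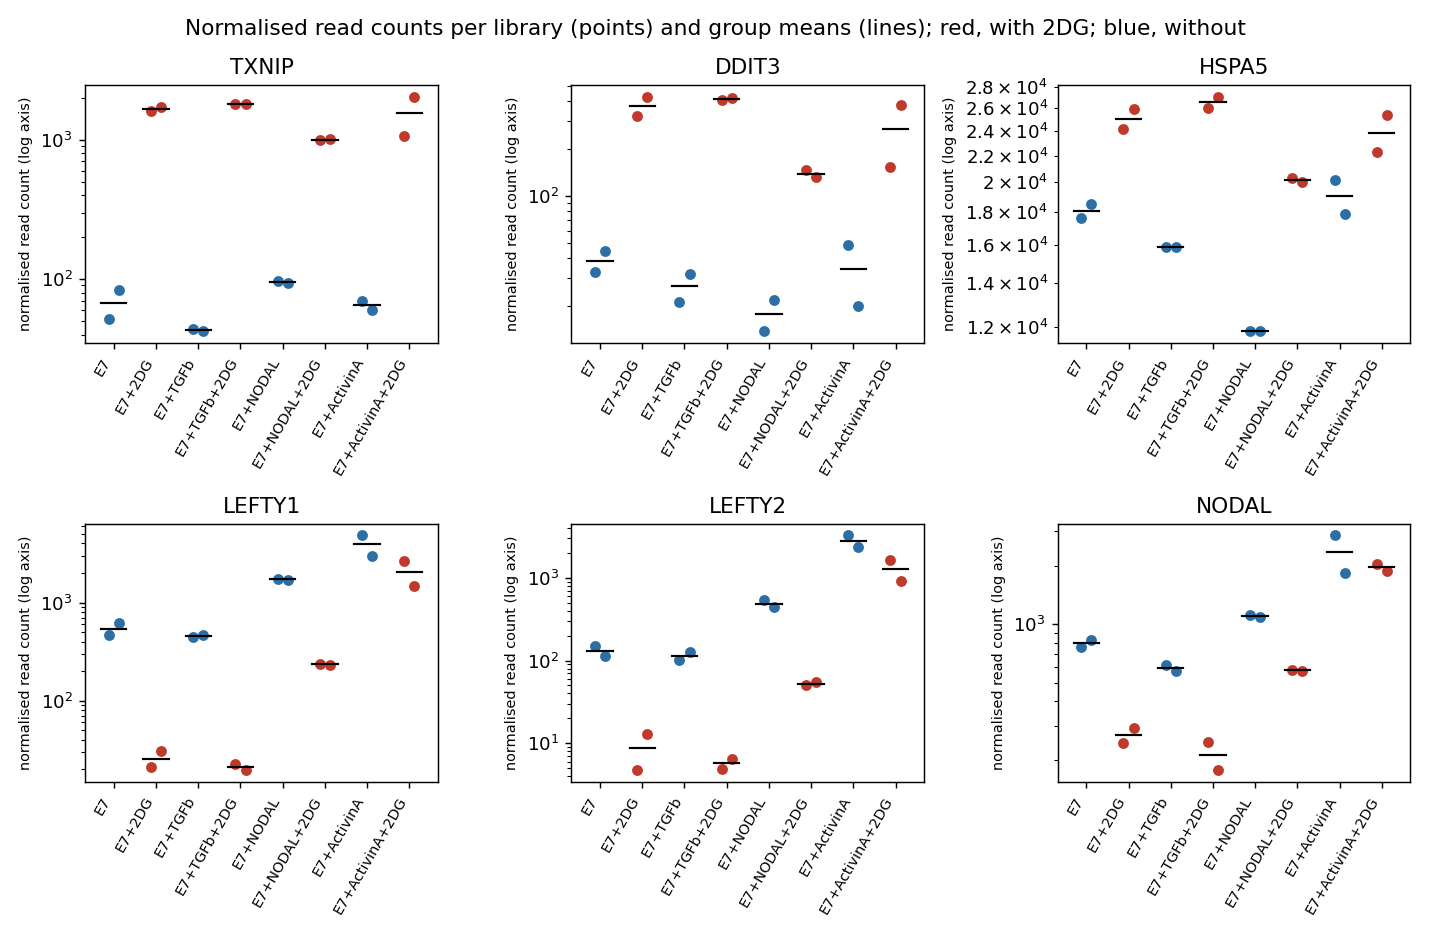
Each panel plots the normalised read count of 1 gene on a log axis for the 8 groups, with points for the 2 libraries (red with 2DG, blue without) and black lines for group means. TXNIP and DDIT3 were called higher with 2DG in each medium, HSPA5 in all but Activin A medium (0.32, adjusted p = 0.094, and called without E7+ActivinA+2DG replicate 1, adjusted p = 0.021, or E7+ActivinA replicate 1, adjusted p = 0.032), and LEFTY1 in E7 went from 538 to 25.7, while in Activin A medium its means were 3910 and 2060.

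TGFb in E7 addressed what restoring the TGFb of E8 medium does. The NODAL targets LEFTY1 (-0.23, adjusted p = 0.62) and LEFTY2 (-0.20, adjusted p = 0.76), NODAL (-0.42, adjusted p = 0.2) and POU5F1 (-0.32, adjusted p = 0.23) did not pass the test. NODAL and POU5F1 passed it without E7+ActivinA replicate 1 (adjusted p = 0.027 and 0.035) or replicate 2 (adjusted p = 0.026 and 0.034). LEFTY1 averaged 454 ± 11.9 with TGFb and 538 ± 106 without it (SD, n = 2). NANOG had -0.16 (adjusted p = 0.37), SOX2 -0.16 (adjusted p = 0.27) and the transcription factor PAX6 -0.38 (adjusted p = 0.72). Only the nuclear oxidative phosphorylation list was called (median -0.39, camera adjusted p = 7.1e-07, and adjusted p = 0.75 with an estimated correlation), with 0 of its 37 members called, also adjusted over the list alone. The log2 fold change rose with transcript length (rho = 0.46 across genes), and the median of the RNA quality histones was -0.49 (camera adjusted p = 0.15). The list of TGFb, Activin and Nodal targets had a median of -0.04, with 0 members called, also adjusted over the list alone (camera adjusted p = 0.64).

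For TGFb in E7 limma called 0 genes, with 3771 at an unadjusted p under 0.05 and a smallest adjusted p of 0.11, while edgeR called 0 and DESeq2 called 295, 204 higher and 91 lower. The count was 3341 without E7+ActivinA replicate 1 and 3350 without its replicate 2. Leaving out all 4 Activin A libraries, after seeing the data, gave 4381. In that fit, with genes named by the same rule, HSPG2 (1.76), IGSF9B (2.13) and the proliferation marker MKI67 (1.13) were higher. POU5F1 (-0.32, adjusted p = 0.0062) and NODAL (-0.42, adjusted p = 0.018) were lower. The S phase list had 0 of 18 higher and 6 lower, and the G2 M phase list 3 of 20 and 7. That fit also called 29 of the 37 nuclear oxidative phosphorylation genes lower and 0 higher, with the length trend left in.

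Activin A in E7 addressed the response to a strong ligand of the pathway. LEFTY2 rose from 131 ± 24.6 to 2820 ± 617 (log2 4.41, SE 0.35, adjusted p = 4.4e-06; SD, n = 2), and LEFTY1 from 538 ± 106 to 3910 ± 1300 (log2 2.83, adjusted p = 1.5e-05). The mesendoderm regulators EOMES (3.50), MIXL1 (3.17) and LHX1 (2.55) rose, as did FGF8 (2.23) and NODAL (1.53). Falls were called in SOX3 (-2.09), SOX21 (-2.54) and POU3F1 (-1.68). In all, 882 genes rose and 793 fell.

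The list of TGFb, Activin and Nodal targets had 8 of 18 higher and 0 lower with Activin A, 9 and 1 adjusted over the list alone (camera adjusted p = 9.6e-07, and adjusted p = 0.033 with an estimated correlation). The mesendoderm list had 8 of 14 higher and 0 lower by either adjustment, the second being adjusted over the list alone (camera adjusted p = 9.6e-07, and adjusted p = 0.033 with an estimated correlation). The BMP target list had 4 of 10 higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.13 with an estimated correlation). The pluripotency core list had 0 of 20 higher and 7 lower, 1 and 9 adjusted over the list alone (camera adjusted p = 0.00025, and adjusted p = 0.03 with an estimated correlation), including PRDM14 (-0.76) and the DNA methyltransferase DNMT3B (-0.70). POU5F1 (0.25, adjusted p = 0.36) and NANOG (0.05, adjusted p = 0.82) did not pass the test, and SOX2 fell by 0.35 on the log2 scale (adjusted p = 0.015). The SOX2 call was lost without E7 replicate 2 (adjusted p = 0.15), and POU5F1 passed the test without E7+ActivinA replicate 2 (0.50, adjusted p = 0.012). The mesendoderm gene T (TBXT) rose by 1.92 (adjusted p = 0.038), a call lost without either replicate of E7 or E7+ActivinA replicate 2 (adjusted p = 0.14 each), or either replicate of E7+NODAL, E7+TGFb, E7+NODAL+2DG or E7+TGFb+2DG (adjusted p from 0.051 to 0.053). The ribosome biogenesis list had 0 of 18 higher and 8 lower, 0 and 11 adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.03 with an estimated correlation). The primed pluripotency list had 3 of 20 higher and 6 lower, 3 and 9 adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.092 with an estimated correlation). The epithelial mesenchymal list had 5 of 13 higher and 0 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.18 with an estimated correlation), with VIM (0.99) and SPARC (0.90). The primed call was lost without E7+ActivinA replicate 1 (adjusted p = 0.078) or replicate 2 (adjusted p = 0.076), and the epithelial mesenchymal call without E7 replicate 2 (adjusted p = 0.092) or E7+ActivinA replicate 1 (adjusted p = 0.076) or replicate 2 (adjusted p = 0.079). The neuroectoderm list had 0 of 12 higher and 3 lower, 2 and 4 adjusted over the list alone, and its median of 0.06 differed in sign from its mean of -0.32 (camera adjusted p = 0.22).

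Other large changes with Activin A were rises in PAG1 (4.15) and LDLRAD4 (2.72), an inhibitor of TGFb signalling, and falls in the retinal reductase DHRS3 (-3.94), INSM1 (-3.32), NEUROG3 (-2.84) and DPP4 (-2.63). The length trend was rho = 0.14 across genes, and the RNA quality histones had a median of -0.04 (camera adjusted p = 0.84). The nuclear oxidative phosphorylation call (camera adjusted p = 0.032, and adjusted p = 0.89 with an estimated correlation) was lost without E7 replicate 2 (adjusted p = 0.68) and took the opposite direction without E7+ActivinA replicate 2 (adjusted p = 0.28). The count of 1675 became 642 without E7 replicate 2, 1002 without E7 replicate 1, 4742 without E7+ActivinA replicate 1 and 2528 without its replicate 2.

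NODAL in E7 addressed the response to the embryonic ligand. LEFTY2 rose from 131 ± 24.6 to 488 ± 65.4 (log2 1.90, SE 0.35, adjusted p = 0.0033; SD, n = 2), and LEFTY1 from 538 ± 106 to 1720 ± 41.5 (log2 1.69, adjusted p = 0.0013). MIXL1 (1.67), GATA2 (1.59), HEY1 (1.24) and FGF8 (1.04) also rose. The metallothionein genes MT1H (-2.68), MT1G (-2.06) and MT1E (-1.68) and the cytochrome gene CYP1B1 (-2.41) fell. In all, 1780 genes rose and 1821 fell.

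The ribosome biogenesis list had 0 of 18 higher and 14 lower with NODAL, 0 and 15 adjusted over the list alone (camera adjusted p = 1.9e-08, and adjusted p = 0.0077 with an estimated correlation), with falls in RRS1 (-0.73), NPM1 (-0.69) and GNL3 (-0.66). The ER unfolded protein response list had 1 of 20 higher and 10 lower, 1 and 12 adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.51 with an estimated correlation), and HSPA5 fell from 18000 ± 572 to 11800 ± 26.5. Nuclear genes of oxidative phosphorylation had 0 of 37 higher and 12 lower, 1 and 20 adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.55 with an estimated correlation). The S phase list had 0 of 18 higher and 8 lower, 0 and 10 adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.51 with an estimated correlation). The heat shock list had 0 of 12 higher and 7 lower by either adjustment, the second being adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.53 with an estimated correlation), including DNAJA1 (-0.82). The hexosamine and N glycosylation list had 1 of 26 higher and 8 lower, 2 and 10 adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.49 with an estimated correlation), and the pluripotency core 0 of 20 higher and 7 lower by either adjustment (camera adjusted p = 0.033, and adjusted p = 0.3 with an estimated correlation). The list of TGFb, Activin and Nodal targets had 6 of 18 higher and 2 lower, 8 and 3 adjusted over the list alone (camera adjusted p = 0.066), and NODAL transcript itself had 0.47 (adjusted p = 0.081), passing the test without E7+ActivinA replicate 1 (adjusted p = 0.0083) or replicate 2 (adjusted p = 0.008). SOX2 fell by 0.25 on the log2 scale (adjusted p = 0.047), a call lost without any 1 library outside the Activin A groups (adjusted p from 0.056 to 0.31).

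Among the largest rises with NODAL were the neural adhesion gene NFASC (2.19), HSPG2 (2.15), PEG3 (2.09), the glutamate receptor gene GRIN2D (2.08) and EBF2 (1.84). The log2 fold change rose with transcript length (rho = 0.24 across genes), and the RNA quality histones had a median of -0.47 (camera adjusted p = 0.066). With each library scaled to the same total, the median over all genes moved by 0.13 and the split went from 1780 higher and 1821 lower (49.4% higher) to 2675 higher and 916 lower (74.5% higher). The count of 3601 became 829 without E7 replicate 2, 1542 without E7+NODAL replicate 1, 874 without E7+NODAL replicate 2, 5675 without E7+ActivinA replicate 1 and 5678 without its replicate 2.

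2DG with TGFb addressed whether the response to 2DG holds in a medium closer to E8. TXNIP rose from 43.1 ± 1.35 to 1800 ± 1.33 (log2 5.35, SE 0.25, adjusted p = 8.3e-08; SD, n = 2), and LEFTY1 fell from 454 ± 11.9 to 21.1 ± 2.1 (log2 -4.37, adjusted p = 9.5e-07). DDIT3 (3.95), DDIT4 (3.90), INHBE (4.10) and TAC1 (4.88) rose. LEFTY2 fell by 4.10 on the log2 scale and MIXL1 by 1.88, and NODAL fell from 595 ± 30.1 to 212 ± 48.6 (adjusted p = 0.00038). In all, 914 genes rose and 730 fell.

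With TGFb present, 2DG raised 25 of the 25 tested members of the ATF4 amino acid response list, also adjusted over the list alone (camera adjusted p = 1.3e-25, and adjusted p = 0.29 with an estimated correlation). The ER unfolded protein response list had 16 of 20 higher and 0 lower, 18 and 0 adjusted over the list alone (camera adjusted p = 2.2e-13, and adjusted p = 0.19 with an estimated correlation), with HERPUD1 (1.57) and HSPA5 (0.74). The S phase list had 0 of 18 higher and 9 lower, 1 and 10 adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.35 with an estimated correlation). The cholesterol list had 0 of 20 higher and 5 lower, 0 and 8 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.35 with an estimated correlation), with HMGCS1 at -0.99. The mesendoderm list had 0 of 14 higher and 4 lower by either adjustment, the second being adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.29 with an estimated correlation). Among nuclear oxidative phosphorylation genes 0 of 37 were called, also adjusted over the list alone (median -0.08, camera adjusted p = 0.31). The length trend was 0 across genes to 2 decimals, and the RNA quality histones had a median of -0.24 (camera adjusted p = 0.27). The count of 1644 became 388 without E7+TGFb+2DG replicate 1, 370 without its replicate 2, 390 without E7+TGFb replicate 1, 402 without its replicate 2, 3150 without E7+ActivinA replicate 1 and 3158 without its replicate 2.

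2DG with Activin A addressed the same response where the pathway is strongly driven. TXNIP rose from 64.8 ± 6.48 to 1550 ± 689 (log2 4.48, SE 0.25, adjusted p = 8.7e-07; SD, n = 2) and INHBE from 46.1 ± 1.45 to 1200 ± 830 (log2 4.47). LEFTY1 averaged 3910 ± 1300 without 2DG and 2060 ± 819 with it, and its log2 fold change of -0.94 did not pass the test (adjusted p = 0.091). LEFTY2 (-1.19, adjusted p = 0.1) and NODAL (-0.22, adjusted p = 0.5) did not pass it either. In all, 247 genes rose and 37 fell.

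With Activin A present, 2DG raised 22 of 25 members of the ATF4 amino acid response list, 24 adjusted over the list alone, and lowered 0 (camera adjusted p = 1.3e-24, and adjusted p = 0.31 with an estimated correlation). The ER unfolded protein response list had 3 of 20 higher and 0 lower, 12 and 0 adjusted over the list alone (camera adjusted p = 8.5e-06, and adjusted p = 0.36 with an estimated correlation), with HERPUD1 (1.02), SYVN1 (0.56) and DNAJC3 (0.56). The glucose transporter SLC2A1 (1.00), VEGFA (1.84), GDF15 (2.43), KLF4 (1.10) and the actin-binding TAGLN (1.38) rose, and ID3 (-1.35) and HMMR (-0.73) fell. The S phase list had 0 of 18 higher and 1 lower, 0 and 11 adjusted over the list alone (camera adjusted p = 2.4e-05, and adjusted p = 0.43 with an estimated correlation). Among mesendoderm genes 0 of 14 were called, also adjusted over the list alone (median -0.51, camera adjusted p = 0.016, and adjusted p = 0.43 with an estimated correlation), and that call was lost without E7+ActivinA+2DG replicate 2 (adjusted p = 0.23) or E7+ActivinA replicate 2 (adjusted p = 0.16). The nuclear oxidative phosphorylation list had 0 of 37 called, also adjusted over the list alone (camera adjusted p = 3.5e-05, and adjusted p = 0.7 with an estimated correlation), and took the opposite direction without E7+ActivinA replicate 1 (adjusted p = 0.77). The log2 fold change rose with transcript length (rho = 0.35 across genes), the RNA quality histones had 1 of 7 lower, also adjusted over the list alone (camera adjusted p = 0.064), and COL6A3 of the stromal list rose by 2.17.

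In E7+ActivinA+2DG the TXNIP counts of replicates 1 and 2 were 1060 and 2030, and the DDIT3 counts were 153 and 379. DDIT3 rose by 2.91 (adjusted p = 0.0056), and without E7+ActivinA+2DG replicate 2 by 2.26 (adjusted p = 0.074). LEFTY1 passed the test at -1.36 (adjusted p = 0.0092) without E7+ActivinA+2DG replicate 1 and at -1.29 (adjusted p = 0.0013) without E7+ActivinA replicate 2. LEFTY2 passed it at -1.59 (adjusted p = 0.032) and -1.41 (adjusted p = 0.01) without the same libraries, and NODAL at -0.54 (adjusted p = 0.012) without E7+ActivinA replicate 2. The count of 284 became 46 without E7+ActivinA+2DG replicate 2, 1621 without its replicate 1 and 5565 without E7+ActivinA replicate 2. It was 146 without E7+2DG replicate 1 or replicate 2, 143 and 140 without E7+TGFb replicate 1 and 2, and 128 without E7+TGFb+2DG replicate 1 or replicate 2. It was 160 and 161 without E7+NODAL replicate 1 and 2, and 125 and 128 without E7+NODAL+2DG replicate 1 and 2.

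2DG with NODAL gave the same comparison in NODAL medium. TXNIP rose from 95.7 ± 2.09 to 1000 ± 14.7 (log2 3.37, SE 0.25, adjusted p = 1.8e-05; SD, n = 2). LEFTY1 fell from 1720 ± 41.5 to 235 ± 3.24 (log2 -2.87, adjusted p = 8.9e-05), and falls were also called in LEFTY2 (-3.18), MIXL1 (-2.35), the matrix protease gene MMP9 (-2.48) and NODAL (-0.93). In all, 520 genes rose and 462 fell.

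With NODAL present, 2DG raised 22 of 25 members of the ATF4 amino acid response list, 24 adjusted over the list alone, and lowered 0 (camera adjusted p = 4.3e-21, and adjusted p = 0.21 with an estimated correlation). Of the ER unfolded protein response list 16 of 20 were higher and 0 lower, 18 and 0 adjusted over the list alone (camera adjusted p = 6.9e-16, and adjusted p = 0.12 with an estimated correlation), and HSPA5 went from 11800 ± 26.5 to 20100 ± 198. The hexosamine and N glycosylation list had 4 of 26 higher and 0 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00088, and adjusted p = 0.19 with an estimated correlation), with STT3A (0.54), a catalytic subunit of oligosaccharyltransferase. Of the TGFb, Activin and Nodal targets 0 of 18 were higher and 7 lower, 1 and 7 adjusted over the list alone (camera adjusted p = 0.00088, and adjusted p = 0.19 with an estimated correlation). Of the mesendoderm list 0 of 14 were higher and 3 lower by either adjustment, the second being adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.21 with an estimated correlation). The S phase list had 1 of 18 higher and 3 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 0.00093, and adjusted p = 0.42 with an estimated correlation). NFASC (-2.16), HEY1 (-2.86) and the proapoptotic BMF (-0.98) fell, and ATF5 (3.43) and PRDM14 (0.73) rose. The length trend was rho = -0.13 across genes, and the RNA quality histones had a median of -0.12 against a mean of 0.05 (camera adjusted p = 0.82).

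For 2DG with NODAL, the call of the NODAL gene was lost without any 1 of the 4 libraries of the comparison, with adjusted p = 0.078 without E7+NODAL replicate 1, 0.088 without its replicate 2, 0.095 without E7+NODAL+2DG replicate 1 and 0.088 without its replicate 2. The count of 982 became 164 without E7+NODAL+2DG replicate 1, 223 without its replicate 2, 256 without E7+NODAL replicate 1, 190 without its replicate 2, 2458 without E7+ActivinA replicate 1 and 2467 without its replicate 2.

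Across the 4 media, 121 genes were called higher with 2DG in each and 10 lower. The largest mean rises were in TAC1 (4.47), TXNIP (4.46), INHBE (4.06), ARRDC4 (3.69), SLC1A4 (3.38), ATF5 (3.33) and DDIT3 (3.26), and the 10 lower genes included PLBD1 (-1.72) and HMMR (-0.88). The counts of 121 and 10 ranged from 32 to 288 and from 0 to 152 with 1 library left out, with 41 and 0 without E7+ActivinA+2DG replicate 2 and 288 and 134 without E7+ActivinA replicate 2. In E7, TGFb and NODAL media together, 269 were called higher in each and 171 lower, from 65 to 492 and from 50 to 410 with 1 library left out. With E7, TGFb medium shared 667 higher genes (chance 133) and 556 lower (chance 108). NODAL medium shared 311 (75.7) and 242 (68.6), with 6 genes in opposite directions, and Activin A medium 215 (36) and 26 (5.49). The Pearson correlation of the log2 response in E7 across genes was 0.59 with that in TGFb medium, 0.64 with Activin A and 0.39 with NODAL. These contrasts share no library, but the order is also that of their length trends (rho = 0.34 in E7, then 0, 0.35 and -0.13).

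**Figure D3:**
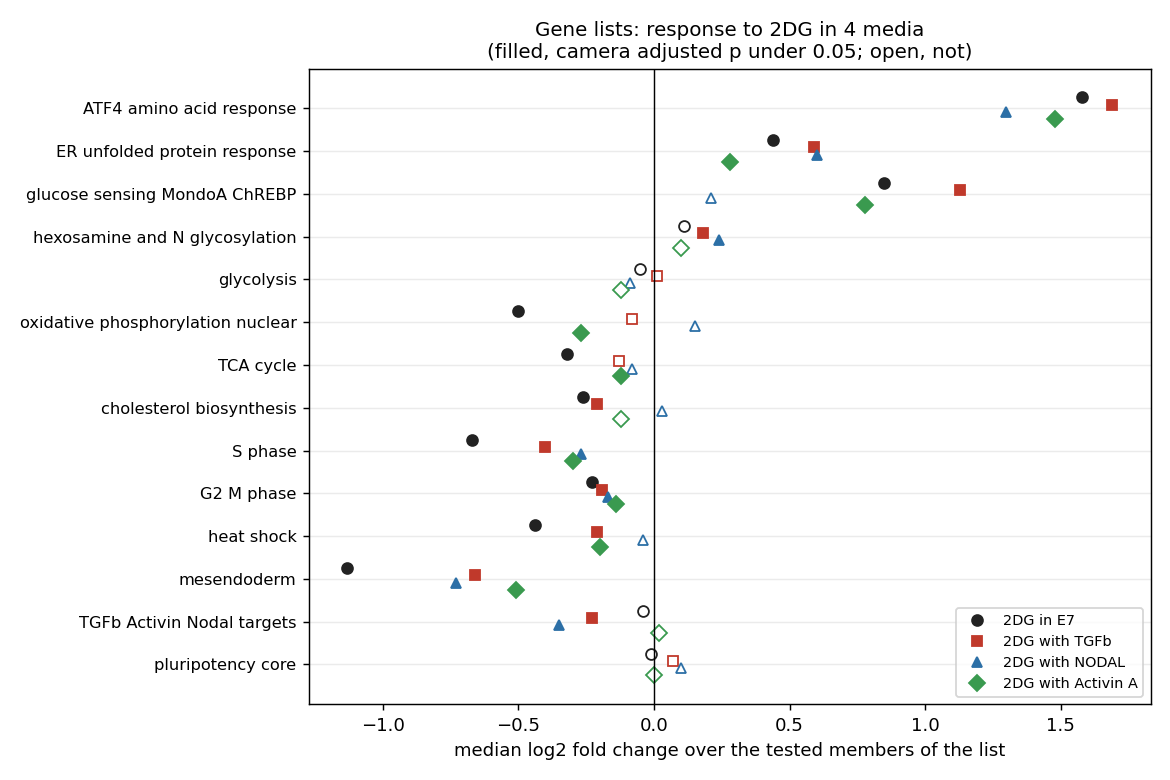
Each marker is the median log2 fold change with 2DG over the tested members of a gene list, in E7 (circle), TGFb (square), NODAL (triangle) or Activin A (diamond) medium, filled where camera gave an adjusted p under 0.05. The ATF4 list sits between 1.30 and 1.69 in the 4 media, and the nuclear oxidative phosphorylation list between -0.50 and 0.15.

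The interaction terms tested whether the response to 2DG differed between a medium with a ligand and E7. For Activin A, LEFTY1 had an interaction of 3.41 (SE 0.37, adjusted p = 0.0052), its log2 response being -4.35 in E7 and -0.94 with Activin A. All 7 genes called were higher, among them the guidance cue gene SEMA3C (1.58), the caveolar coat gene CAV1 (1.19), ERVH48-1 (1.09), LIMA1 (0.87) and NETO2 (0.76). LEFTY2 (2.68, adjusted p = 0.12) and NODAL (1.35, adjusted p = 0.13) did not pass the test. NODAL passed it without E7+ActivinA replicate 1 (1.67, adjusted p = 0.00092) or replicate 2 (1.03, adjusted p = 0.026). LEFTY2 passed it without those libraries (adjusted p = 0.0061 and 0.04), E7+2DG replicate 2 (adjusted p = 0.023) or E7+ActivinA+2DG replicate 2 (adjusted p = 0.038). TXNIP had -0.16 (adjusted p = 0.9) and DDIT3 -0.34 (adjusted p = 0.88).

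For the interaction with Activin A, the list of TGFb, Activin and Nodal targets had 1 of 18 higher and 0 lower, 8 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 0.0011, and adjusted p = 0.33 with an estimated correlation). That call was lost without E7+ActivinA replicate 2 (adjusted p = 0.07). The ribosome biogenesis list had 0 of 18 called, also adjusted over the list alone (median 0.26, camera adjusted p = 0.0011, and adjusted p = 0.12 with an estimated correlation). LEFTY1 kept its call without any 1 of the 16 libraries, but not in a fit of only the libraries of the contrast (adjusted p = 0.55). The count of 7 became 3 without E7 replicate 1, 2 without E7 replicate 2, 2 without E7+2DG replicate 1 or replicate 2, 3 without E7+NODAL replicate 1 or replicate 2, 3 without E7+TGFb replicate 1 or replicate 2, and 4 without E7+NODAL+2DG replicate 1 or replicate 2. It became 38 without E7+ActivinA+2DG replicate 1, 54 without its replicate 2, 2146 without E7+ActivinA replicate 1 and 93 without its replicate 2.

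For the interaction with NODAL, 165 genes were higher and 148 lower. The higher ones included the mitochondrial genes TIMM8B (1.18), TMEM126A (1.15) and COX17 (1.10), the metallothionein MT1G (1.14), the ribosome biogenesis gene GNL3 (0.72) and the chaperones HSPA8 (0.82) and DNAJA1 (0.81). The lower ones included GRIN2D (-1.76), NFASC (-1.73), ADAM19 (-1.38) and the integrin subunit ITGA5 (-1.14). LEFTY1 (1.48, adjusted p = 0.053), TXNIP (-1.27, adjusted p = 0.058) and LEFTY2 (0.68, adjusted p = 0.41) did not pass the test. LEFTY1 passed it without E7 replicate 1 (1.68, adjusted p = 0.046), either replicate of E7+ActivinA+2DG (adjusted p = 0.033 each), E7+ActivinA replicate 1 (adjusted p = 0.0022) or its replicate 2 (adjusted p = 0.0021). TXNIP passed it without E7+ActivinA+2DG replicate 1 (adjusted p = 0.031) or replicate 2 (adjusted p = 0.03), or E7+ActivinA replicate 1 (adjusted p = 0.0075) or replicate 2 (adjusted p = 0.0073).

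In the NODAL interaction the nuclear oxidative phosphorylation list had 1 of 37 higher and 0 lower, 21 and 0 adjusted over the list alone (median 0.66, camera adjusted p = 7.1e-09, and adjusted p = 0.5 with an estimated correlation). The ribosome biogenesis list had 3 of 18 higher and 0 lower, 9 and 0 adjusted over the list alone (camera adjusted p = 6.8e-05, and adjusted p = 0.055 with an estimated correlation), and the heat shock list 3 of 12 higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 6.8e-05, and adjusted p = 0.5 with an estimated correlation). The log2 interaction fell with transcript length (rho = -0.42 across genes), and the RNA quality histones had a median of 0.62 with 0 of 7 called, also adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.5 with an estimated correlation). The histone call was lost without E7+2DG replicate 1 (adjusted p = 0.06) or E7+NODAL replicate 2 (adjusted p = 0.059). The split of 165 higher and 148 lower (52.7% higher) became 117 and 276 (29.8% higher) with each library scaled to the same total. The count of 313 became 0 without E7 replicate 2, and 0 without either replicate of E7+2DG, E7+NODAL, E7+NODAL+2DG, E7+TGFb or E7+TGFb+2DG. It became 691 without E7 replicate 1, 857 without E7+ActivinA+2DG replicate 1, 881 without its replicate 2, 3890 without E7+ActivinA replicate 1 and 3887 without its replicate 2. DESeq2 called 1743 genes and edgeR 287, and with the replicate number as a block limma called 0, with 4163 at an unadjusted p under 0.05.

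For the interaction with TGFb, LEFTY1 had -0.02 (adjusted p = 0.98), LEFTY2 -0.23 (adjusted p = 0.84), NODAL 0.07 (adjusted p = 0.92), TXNIP 0.71 (adjusted p = 0.41), HSPA5 0.27 (adjusted p = 0.41) and POU5F1 0.38 (adjusted p = 0.44). The nuclear oxidative phosphorylation list was called (median 0.43, camera adjusted p = 1.4e-06, and adjusted p = 0.84 with an estimated correlation), as was the heat shock list (median 0.24, camera adjusted p = 0.022, and adjusted p = 0.84 with an estimated correlation), with 0 members called in either, also adjusted over the list alone. The heat shock call was lost without E7 replicate 2 (adjusted p = 0.057), E7+2DG replicate 1 (adjusted p = 0.084), E7+TGFb replicate 2 (adjusted p = 0.062) or E7+TGFb+2DG replicate 2 (adjusted p = 0.11). The log2 interaction fell with transcript length (rho = -0.43 across genes). Limma called 0 genes, with 2023 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each. The count was 1235 without E7+ActivinA replicate 1, 1232 without its replicate 2, and 2457 without the 4 Activin A libraries, a setting added after seeing the data that also called 22 of the 37 nuclear oxidative phosphorylation genes higher and 0 lower.

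2DG alone against TGFb alone set 2DG in E7 beside the medium with TGFb and no 2DG. TXNIP was higher with 2DG, 1670 ± 77.9 against 43.1 ± 1.35 (log2 5.24, SE 0.25, adjusted p = 1.1e-07; SD, n = 2), and LEFTY1 lower, 25.7 ± 6.77 against 454 ± 11.9 (log2 -4.12, adjusted p = 3.1e-06). NODAL (-1.15), MIXL1 (-1.80) and EOMES (-1.81) were lower, while OTX2 (1.03), KLF4 (1.31) and VIM (1.22) were higher. POU5F1 had -0.14 (adjusted p = 0.64), NANOG -0.31 (adjusted p = 0.094) and SOX2 0.14 (adjusted p = 0.34), and NANOG passed the test without E7+ActivinA replicate 1 (adjusted p = 0.015) or replicate 2 (adjusted p = 0.014). In all, 797 genes were higher and 620 lower.

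In that comparison the ATF4 amino acid response list had 23 of 25 higher and 0 lower, 25 and 0 adjusted over the list alone (camera adjusted p = 2.9e-25, and adjusted p = 0.22 with an estimated correlation). The ER unfolded protein response list had 12 of 20 higher and 0 lower, 18 and 0 adjusted over the list alone (camera adjusted p = 1.6e-12, and adjusted p = 0.22 with an estimated correlation), with HERPUD1 (1.54) and XBP1 (0.73). The S phase list had 0 of 18 higher and 8 lower, 1 and 11 adjusted over the list alone (camera adjusted p = 5.3e-06, and adjusted p = 0.31 with an estimated correlation), with RRM1 (-0.65). The mesendoderm list had 0 of 14 higher and 4 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 7e-04, and adjusted p = 0.22 with an estimated correlation). The length trend was rho = 0.05 across genes, and the RNA quality histones had a median of -0.28 (camera adjusted p = 0.24). The count of 1417 became 235 without E7+2DG replicate 2, 524 without its replicate 1, 275 without E7+TGFb replicate 1, 312 without its replicate 2, 3085 without E7+ActivinA replicate 1 and 3090 without its replicate 2.

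TGFb against Activin A compared the ligands at the doses used, 1.74 and 100 ng/mL. LEFTY2 was lower with TGFb, 114 ± 16.8 against 2820 ± 617 (log2 -4.61, SE 0.35, adjusted p = 4.5e-06; SD, n = 2), as were MIXL1 (-3.08), NODAL (-1.95), GATA4 (-2.90) and the stress-inducible GADD45B (-1.68). SOX3 (2.05), SOX21 (2.40), PRDM14 (1.07), DNMT3B (1.08) and HK2 (0.59) were higher with TGFb, HK2 not without E7+TGFb replicate 1 (0.52, adjusted p = 0.076). The list of TGFb, Activin and Nodal targets had 0 of 18 higher and 9 lower by either adjustment, the second being adjusted over the list alone (camera adjusted p = 2.2e-07, and adjusted p = 0.06 with an estimated correlation). The mesendoderm list had 0 of 14 higher and 8 lower, 1 and 9 adjusted over the list alone (camera adjusted p = 6.2e-07, and adjusted p = 0.06 with an estimated correlation), and the BMP targets 0 of 10 higher and 5 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.064 with an estimated correlation). The log2 fold change rose with transcript length (rho = 0.28 across genes), and the RNA quality histones had a median of -0.33 (camera adjusted p = 0.25). In all, 677 genes were higher and 698 lower, and the count of 1375 became 548 without E7+TGFb replicate 1, 564 without its replicate 2 and 6031 without E7+ActivinA replicate 2.

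NODAL against Activin A compared the ligands at the same dose of 100 ng/mL. LEFTY2 was lower with NODAL, 488 ± 65.4 against 2820 ± 617 (log2 -2.52, SE 0.35, adjusted p = 0.0011; SD, n = 2), and so were EOMES (-2.96), T (-1.98), PAG1 (-3.45), GADD45B (-2.13), MIXL1 (-1.50), LEFTY1 (-1.14), NODAL (-1.06) and HSPA5 (-0.69). The LEFTY1 call was lost without E7+ActivinA replicate 1 (adjusted p = 0.051) or E7+NODAL replicate 1 (adjusted p = 0.1) or replicate 2 (adjusted p = 0.12). The T call was lost without E7+ActivinA replicate 2 (adjusted p = 0.084), E7+NODAL replicate 1 (adjusted p = 0.12) or replicate 2 (adjusted p = 0.23), or either replicate of E7+TGFb, E7+NODAL+2DG or E7+TGFb+2DG (adjusted p from 0.053 to 0.055). INSM1 (3.16), DPP4 (2.46), SOX3 (1.84) and POU3F1 (1.83) were higher with NODAL. Among TGFb, Activin and Nodal targets 0 of 18 were higher and 8 lower, 1 and 11 adjusted over the list alone (camera adjusted p = 3.5e-05, and adjusted p = 0.062 with an estimated correlation). Members of the ER unfolded protein response list were higher in 0 and lower in 9 of 20 cases, 1 and 13 adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.16 with an estimated correlation). The FGF ERK target list had 5 of 18 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00078, and adjusted p = 0.062 with an estimated correlation), with EGR1 (2.37) and SPRY1 (0.79). The nuclear oxidative phosphorylation list was called lower (camera adjusted p = 0.0035, and adjusted p = 0.68 with an estimated correlation) but not without E7+NODAL replicate 2 (adjusted p = 0.066), and took the opposite direction without E7+ActivinA replicate 1 (adjusted p = 0.47). The length trend was rho = 0.16 across genes, and the RNA quality histones had a median of -0.39 (camera adjusted p = 0.073).

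In all, 740 genes were higher and 598 lower with NODAL than with Activin A, and with each library scaled to the same total 1169 were higher and 378 lower (75.6% higher against 55.3%). The count of 1338 became 306 without E7+NODAL replicate 1, 305 without its replicate 2, 2062 without E7+ActivinA replicate 1 and 4926 without its replicate 2. Against E7, Activin A and NODAL shared 498 higher genes and 366 lower, with 19 in opposite directions. Chance would give 93.9 and 86.4, leaving out that both contrasts share the E7 libraries. Simulated noise gave, through the shared controls, a Pearson correlation of 0.5 across genes and a covariance of 0.0431, against 0.57 and 0.146 observed. For TGFb and NODAL the covariance was 0.111 against 0.0426. TGFb may act despite 0 calls, so the test decides nothing.

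Positions on hg38 of the genes named most often are as follows. LEFTY1 (ENSG00000243709.1) lies on chromosome 1 from 225886282 to 225911382, LEFTY2 (ENSG00000143768.12) on chromosome 1 from 225936598 to 225941489 and NODAL (ENSG00000156574.9) on chromosome 10 from 70432315 to 70447951. TXNIP (ENSG00000265972.5) lies on chromosome 1 from 145992435 to 145996600, DDIT3 (ENSG00000175197.12) on chromosome 12 from 57516588 to 57521737 and HSPA5 (ENSG00000044574.7) on chromosome 9 from 125234853 to 125241330. All of them are annotated as protein-coding.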

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

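Among the tests in this part, removing the length trend for the NODAL genes and LEFTY1 and leaving out E7+ActivinA+2DG replicate 1 for LEFTY1 were chosen after the result was seen. What a mixture would show was written down before its result, but the share over all risen and fallen genes was taken after that over the genes with larger responses had been seen. The results below are differences in the response to 2DG between a medium with an added ligand and E7, from the interaction terms of the fit. Groups of 2 libraries were too small to test for a library far from the others of its group.

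For Activin A, 7 genes had an interaction, among them LEFTY1 (3.41), SEMA3C (1.58), CAV1 (1.19), ERVH48-1 (1.09), LIMA1 (0.87) and NETO2 (0.76). LEFTY1, which fell with 2DG in E7, kept its call without each library in turn, with adjusted p from 3.8e-05 to 0.03, but not in a fit of only the libraries of the contrast (adjusted p = 0.55). The call of ERVH48-1 was lost without E7 replicate 1 (adjusted p = 0.07) or E7+2DG replicate 2 (adjusted p = 0.076). CAV1 was lost without E7 replicate 2 (adjusted p = 0.062), E7+2DG replicate 1 (adjusted p = 0.051) or E7+2DG replicate 2 (adjusted p = 0.074). SEMA3C, LIMA1 and NETO2 were lost without either replicate of E7, E7+2DG, E7+NODAL+2DG, E7+NODAL or E7+TGFb, with adjusted p from 0.05 to 0.25, and LIMA1 and NETO2 also without either replicate of E7+TGFb+2DG (adjusted p = 0.074 and 0.1).

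For NODAL, 313 genes had an interaction by limma, 287 by edgeR and 1743 by DESeq2. With the replicate number as a block limma called 0, with 4163 at an unadjusted p under 0.05 against 4341 without the block. The largest positive terms were in SNRPGP10 (1.46), DLEU2 (1.39), HMGB1P10 (1.32), TIMM8B (1.18), TMEM126A (1.15), MT1G (1.14), COX17 (1.10) and CD83 (1.09), of which SNRPGP10 and HMGB1P10 are pseudogenes whose reads depend on how shared reads were assigned. The largest negative terms included ZNF469 (-1.83), GRIN2D (-1.76), NFASC (-1.73), SDK2 (-1.66), SLX4 (-1.57), FAM20A (-1.40) and ADAM19 (-1.38). Among list members, the pluripotency gene L1TD1 had 0.80, PHLDA1 -0.73, ITGA5 -1.14, the phosphofructokinase gene PFKP -0.62 and the endoplasmic reticulum enzyme gene H6PD -1.2. TCA cycle genes differed in sign, with OGDH at -0.66, IDH1 at 0.54 and SUCLA2 at 0.52. CYCS had 0.79, DPM1 1, DNAJB11 0.59 and IDI1 0.92. Ribosome biogenesis genes GNL3 (0.72), NOP58 (0.55) and WDR12 (0.49) were higher, as were the chaperone genes HSPA8 (0.82), DNAJA1 (0.81) and HSPD1 (0.60).

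For TGFb, the lists with an interaction were nuclear oxidative phosphorylation (median 0.43, adjusted p = 0.84 with an estimated correlation) and heat shock (median 0.24, adjusted p = 0.84 with an estimated correlation). For Activin A they were the TGFb, Activin and Nodal targets (median 0.45, adjusted p = 0.33 with an estimated correlation), trophoblast and amnion (0.57, adjusted p = 0.34 with an estimated correlation) and ribosome biogenesis (0.26, adjusted p = 0.12 with an estimated correlation). Nuclear oxidative phosphorylation (0.22, adjusted p = 0.75 with an estimated correlation), cholesterol (0.15), S phase (0.30) and heat shock (0.23, each adjusted p = 0.69 with an estimated correlation) were called as well. For NODAL they were epithelial mesenchymal (-0.38, adjusted p = 0.26 with an estimated correlation), TCA cycle (0.21, adjusted p = 0.59 with an estimated correlation), S phase (0.29, adjusted p = 0.58 with an estimated correlation) and ribosome biogenesis (0.48, adjusted p = 0.055 with an estimated correlation). Nuclear oxidative phosphorylation (0.66), cholesterol (0.34), heat shock (0.34) and the RNA quality histones (0.62) were also called with NODAL, each with adjusted p = 0.5 with an estimated correlation.

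Several of these list calls were lost when 1 library was left out, the heat shock call for TGFb among them. For Activin A, leaving out E7+ActivinA replicate 2 ended the calls of the TGFb, Activin and Nodal targets (adjusted p = 0.07), trophoblast and amnion (adjusted p = 0.25), S phase (adjusted p = 0.26) and heat shock (adjusted p = 0.29), and turned nuclear oxidative phosphorylation to the opposite direction (adjusted p = 0.38). Leaving out E7+ActivinA+2DG replicate 1 ended cholesterol (adjusted p = 0.31), S phase (adjusted p = 0.42), heat shock (adjusted p = 0.11) and nuclear oxidative phosphorylation (adjusted p = 0.51). Cholesterol was lost without E7+2DG replicate 1 (adjusted p = 0.099) or E7+ActivinA replicate 1 (adjusted p = 0.15), S phase without E7+2DG replicate 1 (adjusted p = 0.05), and nuclear oxidative phosphorylation without E7 replicate 2 (adjusted p = 0.41) or E7+2DG replicate 1 (adjusted p = 0.12). For NODAL, leaving out E7+2DG replicate 1 ended TCA cycle (adjusted p = 0.11), and cholesterol, S phase and the histones (adjusted p = 0.06 each), and leaving out E7+NODAL replicate 2 ended the histones and TCA cycle (adjusted p = 0.059 each). TCA cycle was lost as well without E7 replicate 1 (adjusted p = 0.09), E7+NODAL+2DG replicate 1 (adjusted p = 0.098), E7+NODAL replicate 1 (adjusted p = 0.054) or either replicate of E7+TGFb+2DG (adjusted p = 0.051 each).

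The genes whose response to 2DG differed with NODAL tended to differ in length, with a median longest transcript of 2471 nt for those higher, 5470 nt for those lower and 3342 nt for all tested. A length trend between libraries could make such a set, but after its removal 287 of the 313 genes were still called in the same direction, with a median signed term of 0.66 against 0.81, which argues against length as the whole cause. Whether the E7 and E7+2DG libraries alone made the pattern cannot be told apart from a response to NODAL. The 2DG response with NODAL less that with TGFb uses neither group. Its signed median over the 313 genes was 0.4, a ratio of 0.5 to the interaction. Choosing genes by the same NODAL libraries gives 0.5 from noise alone if groups are equally noisy. The SD of replicate log2 differences was 0.27 in E7 and 0.18 in E7+NODAL, so the ratio decides nothing. A change in the 2DG response brought by NODAL stays open and was not tested further, and all 313 calls were lost with the replicate block.

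In E7+ActivinA+2DG, replicate 1 responded less than replicate 2, with a median log2 response of 0.44 against 0.91 over genes risen in the other 3 media and -0.16 against -0.49 over genes fallen. RNA of cells without 2DG mixed into replicate 1 could lower both alike, at 1 share. The median share needed was 0.6 over all 171 fallen genes (0.52 to 0.64, 95% interval from 1000 bootstraps). Over all 269 risen genes it was 0.65 (0.62 to 0.66). Over the 27 fallen and 119 risen with absolute log2 responses of at least 1 in replicate 2 the intervals were 0.48 to 0.63 and 0.66 to 0.7. These treat genes as independent and are too narrow to test for 1 share, so a mixture is neither excluded nor established. The ratio of the log2 responses was 0.46 over 440 genes and 0.45 after the length trend was removed, which argues against length, and no biological explanation was tested for a difference between replicates.

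LEFTY1 differed in its response to 2DG between Activin A medium and E7, by 3.41 (SE 0.37, adjusted p = 0.0052). The weak response of E7+ActivinA+2DG replicate 1 could have made this, but without that library the term was 2.99 (SE 0.35, adjusted p = 0.0049). With the length trend removed it was 3.33 (SE 0.27, adjusted p = 4.1e-05), so the tables argue against both as the whole cause, though the call itself was lost in a fit of only the libraries of the contrast (adjusted p = 0.55). Whether Activin A itself changed the response stays open, since deciding it takes new cultures of the same 4 groups, and reads shared between LEFTY1 and LEFTY2 were not tested.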

How the results depend on the processing

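Removing the length trend, weighting the libraries and leaving out the 4 Activin A libraries were chosen after the data were seen, as were the contrasts of a ligand with 2DG present. Named genes had 917 results (852 with a mean of at least 50, 589 without the Activin A libraries). Direction changed for 0 calls and up to 12 uncalled results (quantile normalization). Calls were lost for 7 with TMM factors, 45 with equal totals, 69 with quantile normalization, 29 with edgeR, 18 with DESeq2, 92 with a replicate block, 139 with library weights, 239 with only the libraries of the contrast, 23 with the length trend removed and from 2 to 242 with 1 library left out. Counts of genes called stayed within 1.5 times under equal totals, quantile normalization, either pseudocount, no filter, robust fitting and edgeR. Of 102 gene set calls, 5 held with an estimated correlation, 80 with fry, 91 with the length trend removed and 84 to 101 with 1 library left out. The cause was not tested for any change below, except where a fold minimum or fewer libraries makes it by construction. Depth limits genes with few reads most, since counting error is largest there.

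With an absolute log2 fold change of at least 1 the counts were 1027 for 2DG in E7, 510 for Activin A in E7, 516 for NODAL in E7, 448 for 2DG with TGFb, 154 for 2DG with Activin A and 315 for 2DG with NODAL. They were 4 and 80 for the interactions with Activin A and NODAL, 393 for 2DG alone against TGFb alone, 512 for TGFb against Activin A, 370 for NODAL against Activin A, and 512 and 57 for Activin A and NODAL with 2DG present. DESeq2 gave 295 for TGFb in E7, 606 for 2DG with Activin A, 43 and 1743 for the interactions with Activin A and NODAL, and 278 for NODAL with 2DG present. TMM factors gave 11 for the interaction with Activin A, and a mean of at least 50 gave 12 for it and 847 for that with NODAL. With a replicate block the interaction with NODAL had 0 genes by limma, with 4163 at an unadjusted p under 0.05.

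Without the Activin A libraries the counts were 7590 for 2DG in E7, 4381 for TGFb in E7, 6479 for NODAL in E7, 4109 for 2DG with TGFb, 3388 for 2DG with NODAL, 2457 and 4800 for the interactions with TGFb and NODAL, 3995 for 2DG alone against TGFb alone and 2952 for NODAL with 2DG present. With only the libraries of the contrast they were 2435 for TGFb in E7, 96 for Activin A in E7, 6332 for 2DG with TGFb, 3 for 2DG with Activin A and 4865 for 2DG with NODAL. The same setting gave 1525, 0 and 3940 for the interactions with TGFb, Activin A and NODAL, 4342 for 2DG alone against TGFb alone, 102 for TGFb against Activin A, 0 for NODAL against Activin A and 3375 for NODAL with 2DG present. The library weights were 0.22 for E7+ActivinA and 1.91 for E7+TGFb, and gave 3265 for TGFb in E7, 393 for Activin A in E7, 5371 for 2DG with TGFb, 29 for 2DG with Activin A and 4518 for 2DG with NODAL. They gave 1508, 1 and 4201 for the interactions with TGFb, Activin A and NODAL, 4248 for 2DG alone against TGFb alone, 503 for TGFb against Activin A, 232 for NODAL against Activin A and 3058 for NODAL with 2DG present. With the length trend removed they were 2697 for Activin A in E7, 2889 for 2DG with TGFb, 739 for 2DG with Activin A, 2008 for 2DG with NODAL, 55 and 1423 for the interactions with Activin A and NODAL, 2706 for 2DG alone against TGFb alone, 2518 for NODAL against Activin A and 439 for NODAL with 2DG present.

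With 1 library left out the counts ranged from 1586 to 7003 for 2DG in E7, 0 to 3350 for TGFb in E7, 642 to 4742 for Activin A in E7, 829 to 5678 for NODAL in E7, 370 to 3158 for 2DG with TGFb, 46 to 5565 for 2DG with Activin A and 164 to 2467 for 2DG with NODAL. They ranged from 0 to 1235, 2 to 2146 and 0 to 3890 for the interactions with TGFb, Activin A and NODAL, 235 to 3090 for 2DG alone against TGFb alone, 548 to 6031 for TGFb against Activin A and 305 to 4926 for NODAL against Activin A. With 2DG present they ranged from 624 to 1948 for Activin A and 11 to 1767 for NODAL, and gave 0 for TGFb throughout. The nuclear oxidative phosphorylation list took the opposite direction in 4 contrasts when an E7+ActivinA library was left out, with adjusted p over all left-out libraries from 4.1e-07 to 0.68 for Activin A in E7 (0.28 without replicate 2), 1.2e-09 to 0.77 for 2DG with Activin A (0.77 without replicate 1), 1.6e-08 to 0.51 for the interaction with Activin A (0.38 without replicate 2) and 8.5e-09 to 0.47 for NODAL against Activin A (0.47 without replicate 1).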

Other observations

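The contrasts in this part were added after the data had been seen, and ask what each ligand does when 2DG is present. Activin A with 2DG raised LEFTY2 from 8.9 ± 5.87 to 1270 ± 496 (log2 7.09, SE 0.35, adjusted p = 3.4e-08; SD, n = 2), LEFTY1 from 25.7 ± 6.77 to 2060 ± 819 (log2 6.24) and NODAL from 268 ± 33.6 to 1970 ± 116 (log2 2.88). HEY1 (5.21), MIXL1 (4.43), FGF8 (3.67), EOMES (3.43) and GATA2 (3.19) rose, and OLIG3 (-4.33), NEUROG3 (-2.44), HES3 (-2.15) and SOX3 (-1.55) fell. The neuroectoderm list had 1 of 12 higher and 3 lower, 3 and 4 adjusted over the list alone (camera adjusted p = 0.13). PAX6 had 1.87 (adjusted p = 0.07), and passed the test without E7+2DG replicate 2 (2.86, adjusted p = 0.011) or either replicate of E7+ActivinA (adjusted p = 0.041 each). T rose by 2.78 (adjusted p = 0.0049), a call lost without E7+2DG replicate 2 (adjusted p = 0.073) or E7+ActivinA+2DG replicate 1 (adjusted p = 0.075). In all, 713 genes rose and 544 fell. The TGFb, Activin and Nodal targets had 9 of 18 higher and 0 lower, 11 and 1 adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.028 with an estimated correlation). Of the mesendoderm list 8 of 14 were higher and 0 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 5.1e-09, and adjusted p = 0.028 with an estimated correlation). The primed pluripotency list had 1 of 20 higher and 7 lower, 2 and 9 adjusted over the list alone (camera adjusted p = 0.0014, and adjusted p = 0.036 with an estimated correlation), with a fall in USP44 (-1.32). TXNIP had -0.18 (adjusted p = 0.81) and HSPA5 -0.07 (adjusted p = 0.79). The count of 1257 became 663 without E7+2DG replicate 1, 624 without its replicate 2, 759 without E7+ActivinA+2DG replicate 1, 1943 without E7+ActivinA replicate 1 and 1948 without its replicate 2.

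NODAL with 2DG raised LEFTY1 from 25.7 ± 6.77 to 235 ± 3.24 (log2 3.17, SE 0.26, adjusted p = 5.3e-05; SD, n = 2), FGF8 (1.57), the lipase gene ABHD12B (1.53) and NODAL (1.11). The NODAL call was lost without E7+2DG replicate 1 (adjusted p = 0.16) or replicate 2 (adjusted p = 0.08), or E7+NODAL+2DG replicate 1 (adjusted p = 0.16) or replicate 2 (adjusted p = 0.15). The apelin receptor ligand gene APELA fell from 1550 ± 4.3 to 485 ± 22.6 (log2 -1.67), as did CYP1B1 (-2.40), LIMCH1 (-2.47) and OLIG3 (-1.94). LEFTY2 rose by 2.58 (adjusted p = 0.0052), a call lost without E7+NODAL+2DG replicate 1 (adjusted p = 0.072) or replicate 2 (adjusted p = 0.085). In all, 71 genes rose and 35 fell (67% higher), and 107 rose and 28 fell with each library scaled to the same total (79.3% higher). The mesendoderm list had 2 of 14 higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation). The length trend was rho = -0.34 across genes. The count of 106 became 16 without E7+2DG replicate 1, 11 without its replicate 2, 15 without E7+NODAL+2DG replicate 1, 11 without its replicate 2, 61 without E7+TGFb+2DG replicate 1 or replicate 2, 56 without E7+NODAL replicate 1 or replicate 2, 56 without E7+TGFb replicate 1 and 55 without its replicate 2. It became 299 without E7+ActivinA+2DG replicate 1, 300 without its replicate 2, 1767 without E7+ActivinA replicate 1 and 1755 without its replicate 2. TGFb with 2DG called 0 genes by limma, with 273 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each.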
